A study of Mus musculus with 6 samples.

How the data were processed

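Whole-testis RNA was profiled in 6 mice, 3 treated with vehicle and 3 with the inhibitor, as given by the sample labels. Per the labels' protocols, libraries were prepared from 500 ng of total RNA with a directional kit after selection of polyadenylated RNA, and sequenced as single-end reads of 81 nt. The submitters' processing notes list cutadapt 1.8, TopHat2 2.0.13, Cuffdiff 2.2.1 and the genome build mm10. The role of each tool, the gene annotation and the strand setting of the counting are not given in the sources used here, so fragments of overlapping genes on opposite strands may not be separated. The deposited table holds, for each of 23361 genes and each library, the fragments assigned to the gene and a value scaled to transcript length and library size (FPKM).

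The fragment values are expected counts as deposited by the authors, before any scaling by library size: 98.8% of 140166 values were whole within a tolerance of 1e-06, and 337 genes held a value that was not. They were rounded to whole numbers. The FPKM values were scaled by the authors' software and deposited alongside; they were used in alternatives on the log2 scale only. In 7 genes, 9 values carried a failed status in the deposited table. Library totals ranged from 23144295 to 43127890 fragments. No mitochondrially encoded gene was among those tabulated, so that list could not be examined.

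Genes were tested with edgeR 4.0.16 in R 4.3.3: low counts were filtered with filterByExpr, libraries were normalised by the trimmed mean of M values, and the robust quasi-likelihood F-test compared the groups, two-sided, with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 8.0%. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 24 lists that had at least 3 tested genes. For a list's level per mouse, log2 CPM with a prior count of 2 was averaged over its members. Fold changes are inhibitor over control.

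Before the data were examined, 26 lists with 452 symbols were fixed, of which 428 symbols matched the table, 7 through an older symbol. The rule for named genes was fixed then too: Gdnf, Gfra1 and Ret; the 8 largest rises and 8 largest falls among genes past the threshold with mean log2 CPM of at least 0 and no overlap between the groups, without unnamed loci; and up to 4 members of each list with the smallest p. For lists that did not pass, 2 members were named instead of 4, a choice made after the data were seen, and 1 gene the rule names is not reported here. Genes outside the rule are identified as such where they appear. The main test was also fixed then, and so were all alternatives except those on transcript length and GC content and on single members of lists.

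Gene positions, transcript lengths and GC content came from the longest transcript of each gene in GENCODE M21, whose assembly, GRCm38, is the same as mm10. Of the tested genes, 93.3% had a length. The length and GC correction fitted, for each library, a loess surface (span 0.5) of log2 CPM deviations on length and GC over genes with mean log2 CPM above 1, and used it as an offset in the same edgeR model. Genes without a length received no offset, so their fold changes were left uncorrected.

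As alternatives, libraries were scaled by relative log expression (RLE) size factors in edgeR or by library totals alone. Other tests were DESeq2 1.42.0, limma-voom, and limma on log2(FPKM + 1) and log2(FPKM + 0.1). Other gene sets had no filter on low counts, at least 50 counts in 3 libraries, or the 50 most abundant genes removed. Further alternatives were the mouse number as a block, each mouse left out in turn, an estimated inter-gene correlation, and fry. The DESeq2 test gave no adjusted p for 4523 genes.

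The procedure was tested on simulated data drawn for the 16658 genes of this comparison from their means, library sizes and dispersions, with 200 genes changed. Of the 100 genes changed 1.5-fold, 59% were recovered, and of the 100 changed 3-fold, 91%. With gene-wise dispersions 25 of 178 calls were false, above the nominal rate, and with dispersions that followed the mean trend 7 of 171 were. A planted shift of −0.5 in the undifferentiated list was recovered with a median of −0.47. In 10 runs without any change, 37 genes were called and 1 list passed in total. Each gene was drawn independently, so the list test was not tried with the inter-gene correlation that real lists may have. When the length and GC trend of the real libraries was added, 42 calls were false without its removal and 9 with it. The added trend came from the correction's own model, so this does not show how well trends of other shapes are removed.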

Results

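Gene expression was measured in whole testes of 6 adult mice of the C57BL/6J strain, aged about 120 days, by sequencing of polyadenylated RNA. All 6 animals were homozygous for the V805A substitution in Ret, the receptor tyrosine kinase that transmits the signal of glial cell line-derived neurotrophic factor (GDNF). The substitution makes the kinase sensitive to the small molecule 1NaPP1-HCl, so that GDNF signalling can be inhibited chemically in the living animal. For 9 days, 3 mice received daily injections of vehicle (controls) and 3 received the inhibitor in vehicle. After 5 days without injections, testes were collected on day 14. The libraries held 24788698, 43127890 and 29227418 fragments assigned to genes in controls 1, 2 and 3, and 29069387, 23144295 and 28871412 in inhibitor mice 1, 2 and 3. A gene at 1 CPM (fragment counts scaled to library size) therefore rested on between 23.1 and 43.1 fragments per library. The deposited labels give each library as a separate mouse, and within each group all pairs of libraries differed by more than counting noise, with chi-square values of 4.23 to 13.08 per degree of freedom.

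The comparison of inhibitor with control mice asked how the testis transcriptome differed after treatment meant to inhibit GDNF signalling and 5 days without it. No measure of Ret kinase activity is among these data. The samples include no inhibitor-treated mice without the substitution, so effects of the compound on other targets cannot be told apart from those on Ret. Ret RNA itself fell in the inhibitor mice, from 2.17 ± 0.294 CPM to 0.579 ± 0.086 CPM (SD, n = 3 per group), a 3.77-fold lower level. Its log2 fold change was −1.91 (SE 0.231, adjusted p = 0.020, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The Ret gene lies on chromosome 6 from 118151745 to 118197718 on the reverse strand of GRCm38, and its level rested on 57, 105 and 54 fragments in the controls and 14, 15 and 17 in the inhibitor mice. Without control 1, control 2, inhibitor 1 or inhibitor 2 Ret did not pass (adjusted p up to 0.157 in the edgeR test), with log2 fold changes of −2.01 to −1.80 over all mice left out in turn. Gfra1, which encodes the co-receptor that binds GDNF, stood at 3.88 ± 0.479 CPM in controls and 3.20 ± 0.203 CPM in inhibitor mice (log2 fold change −0.28, SE 0.152), and this difference did not pass (adjusted p = 0.366 by the same edgeR test). Gdnf, the ligand, was at 1.27 ± 0.060 and 1.37 ± 0.232 CPM, with adjusted p = 0.827 in the edgeR test. Of the 8 tested genes in the list of GDNF family ligands and receptors, Ret alone passed, and the list itself did not (camera adjusted p = 0.054). It lay near the threshold and passed in several alternatives, among them those without control 2 or without inhibitor 2 (adjusted p = 0.015 to 0.634 over all alternatives). Without Ret the median log2 fold change of the other 7 members was −0.02.

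**Figure D1:**
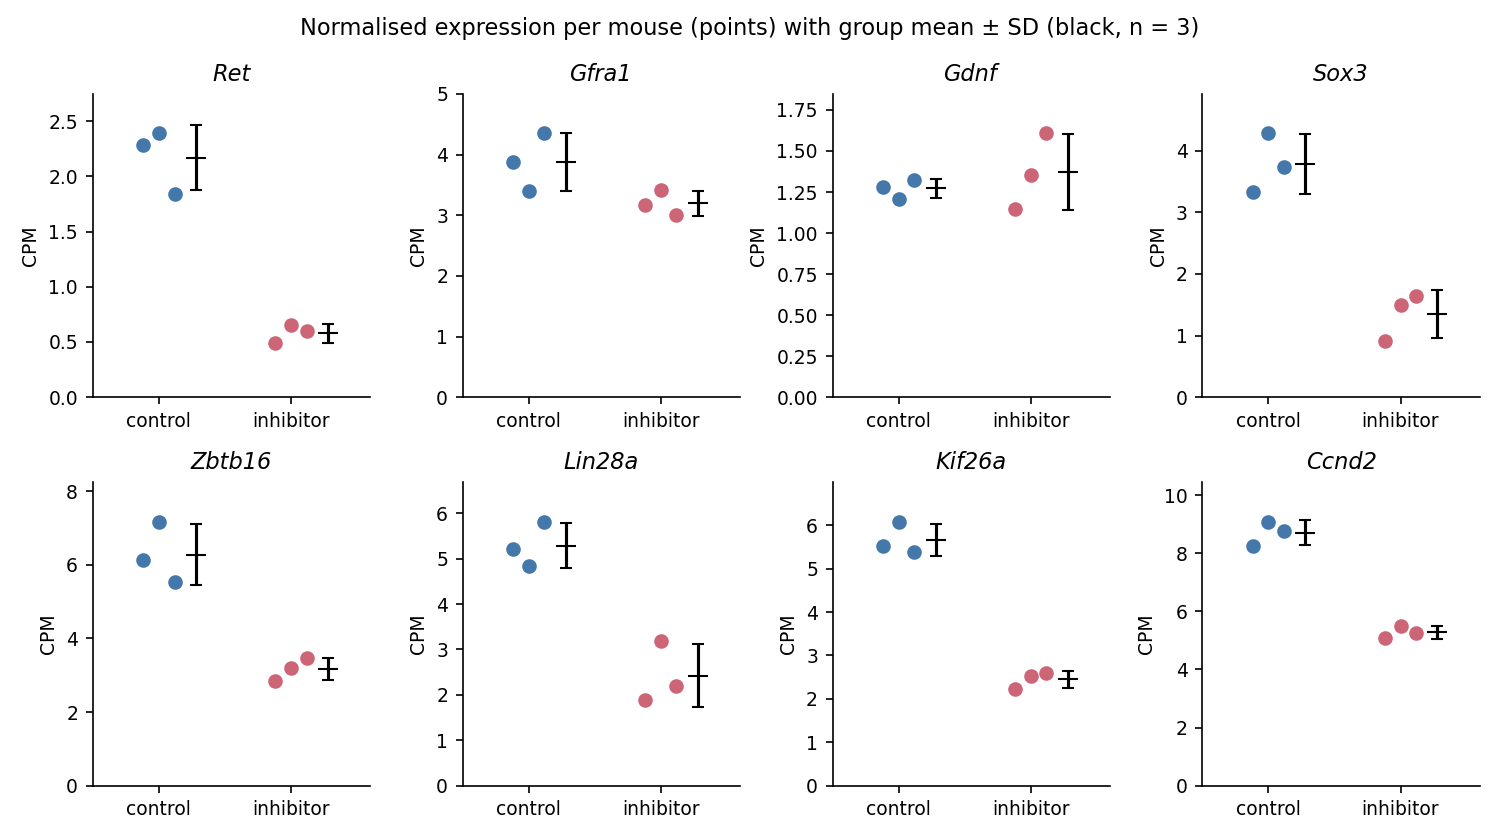
Expression of Ret, Gfra1, Gdnf, Sox3, Zbtb16, Lin28a, Kif26a and Ccnd2 in each mouse (points; vertical axis, CPM after normalisation, starting at 0), with the mean and SD of each group of 3 in black. Ret values in the 3 inhibitor mice lay between 0.487 and 0.656 CPM, below the control range of 1.84 to 2.39 CPM, whereas the Gdnf values of the groups overlapped.

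Among genes past the threshold with a mean log2 CPM of at least 0, those with the largest falls were expressed at low levels in the testis. Of these, 3 (Sox3, Lin28a and Zbtb16) are in the fixed list of undifferentiated spermatogonia, the small mitotic population that includes the stem cells. Ret is in the fixed list of stem cell-enriched spermatogonial markers. After Ret, the largest falls among the genes past the threshold with that mean level were in Prtg (log2 fold change −1.70), which encodes a cell surface protein of the immunoglobulin superfamily, and Foxf1 (−1.68), a forkhead transcription factor. They were followed by Sox3 (−1.50), an X-linked transcription factor of undifferentiated spermatogonia, and Kif26a (−1.21), an unconventional kinesin known to restrain GDNF-Ret signalling in enteric neurons. Lin28a (−1.13) encodes an RNA-binding protein that blocks maturation of the let-7 microRNAs, Trim71 (−1.11) is a let-7 target that encodes an RNA-binding protein, and Zbtb16 (−0.99) encodes a transcription factor needed to maintain the stem cell pool. Kif26a went from 5.66 ± 0.373 to 2.45 ± 0.197 CPM, Sox3 from 3.78 ± 0.481 to 1.34 ± 0.390 CPM, and Zbtb16 from 6.28 ± 0.827 to 3.17 ± 0.307 CPM (SD, n = 3 per group). The named genes that rose changed by less. They were Sec11c (0.54), a signal peptidase subunit, Klk1b8 (0.45), Daf2 (0.36), Bcap29 (0.33), a protein of the endoplasmic reticulum, and Gdpd1 (0.29). Klk1b8 and Daf2 have near-identical relatives in the mouse genome, and their values are uncertain to the extent that fragments were divided among copies.

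In total, 16 genes fell and 10 rose among 16658 tested (edgeR quasi-likelihood test, adjusted p threshold 0.05), and 5 of the genes that rose are unnamed loci. Scaling by library totals alone gave 23 lower and 4 higher. Ccnd2, a cyclin gene named as a member of a fixed list, fell by 0.73 on the log2 scale. The other genes that fell, named here after their values were seen, were Bahcc1 (−0.96), Akap13 (−0.60), Ski (−0.50), Igf1r (−0.50), Fasn (−0.37), Plxna1 (−0.32) and Guca2b. With each library's trend on transcript length and GC content removed, a correction chosen after the data were seen, only 8 of the 21 named genes past the threshold stayed past it: Ret, Prtg, Sox3, Kif26a, Zbtb16, Guca2b, Daf2 and Bcap29. Daf2 had no transcript length, so its fold change was left uncorrected (log2 fold change 0.358 in both fits). Of the 13 that did not stay past the threshold, Fasn and Plxna1 shrank most, to −0.16 and −0.13 (edgeR adjusted p = 0.188 and 0.329). The other 11, Lin28a, Trim71, Foxf1 and Ccnd2 among them, had edgeR adjusted p from 0.053 to 0.127. Of these, Lin28a (−1.11), Foxf1 (−1.66), Ccnd2 (−0.66) and Sec11c (0.54) kept log2 fold changes close to the uncorrected ones. The others of the 11 shrank by more, among them Trim71 to −0.94 and Klk1b8 to 0.30. Guca2b encodes the gut hormone uroguanylin (chromosome 4, 119656607 to 119658954, GRCm38), and it had 28, 35 and 52 fragments in the controls and 0 in each inhibitor mouse. Against a floor of 3 counts over the inhibitor group, its level was at least 31.3-fold lower, a bound that covers counting error only. At an unadjusted p threshold of 0.05, 1571 genes were higher and 1412 lower, where chance alone would give 833 in all. In 3823 genes (22.9%) the values of the groups did not overlap, against 10% by chance. Such counts vary widely around chance where many genes move together, so the excess alone does not show an effect of treatment. With the length and GC trend removed, 1243 genes were higher and 1015 lower at the unadjusted threshold. The number of calls depended on each mouse: it was 0 in both directions without control 1, control 2, inhibitor 1 or inhibitor 2, 3 higher and 7 lower without control 3, and 1470 higher and 935 lower without inhibitor 3. DESeq2 called 364 genes higher and 167 lower, and limma on the deposited FPKM values, as log2(FPKM + 1), called 0 in either direction, with 1603 higher and 1179 lower at the unadjusted threshold.

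Undifferentiated spermatogonial genes fell as a group (median log2 fold change −0.48, camera adjusted p = 4.7e-10), although with an inter-gene correlation estimated from the data the list did not pass (adjusted p = 0.184). Of its 15 tested members 13 were lower in the inhibitor mice and 3 passed on their own (Sox3, Zbtb16 and Lin28a), or 7 adjusted over the list alone. Foxo1, a transcription factor involved in stem cell maintenance, had a log2 fold change of −0.48 (SE 0.103, edgeR adjusted p = 0.081), and it was among the 7. Sall4, Glis3 and Sall1, named after their values were seen, complete that number. Sall4 had the lowest estimate of the list, 5.14 ± 1.19 CPM in controls and 1.63 ± 0.757 CPM in inhibitor mice (log2 fold change −1.66, edgeR adjusted p = 0.083). The mean log2 CPM of the list was 2.16 ± 0.115 in controls and 1.58 ± 0.094 in inhibitor mice (SD, n = 3 per group), without overlap. An exact two-sided permutation test of these means gave p = 0.1, the smallest value that 3 against 3 mice allow. In the camera test with its preset correlation the list passed without any one of the mice (medians −0.52 to −0.35).

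Genes of differentiating spermatogonia, the next stage of the lineage, fell as a list with a smaller median (log2 fold change −0.15, camera adjusted p = 0.002, or 0.293 with an estimated correlation). In this list 11 of 13 members were lower, none passed over all genes and 5 passed adjusted over the list alone. These 5 were the DNA methyltransferase gene Dnmt3b (−0.53), the retinoic acid-binding protein gene Crabp1 (−0.64), the transcription factor gene Sohlh1 (−0.66), the maintenance methyltransferase gene Dnmt1 (−0.17) and the cyclin gene Ccnd3 (−0.14), the last named after its values were seen. With the length and GC trend removed, Dnmt1 and Ccnd3 were at −0.05 and −0.045 (edgeR adjusted p = 0.731 and 0.686). In controls Dnmt3b, Crabp1 and Sohlh1 stood at 8.98, 4.03 and 4.19 CPM. The 2 members that were higher, Ddx4 (0.07) and Dmrtb1 (0.11), stood at 617 and 518 CPM. A median over genes of such unlike levels in whole testis does not show whether this stage changed less than undifferentiated spermatogonia. X- and Y-linked spermatogonial genes did not pass as a list (median −0.05, adjusted p = 0.271), and their members with the smallest p were Uba1y (−0.24) and Tex13 (−0.30). With the same trend removed that list passed (median −0.15, adjusted p = 0.006), but not with an estimated correlation (adjusted p = 0.658).

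GDNF-responsive genes fell as a list, with 13 of 15 tested members lower and a median log2 fold change of −0.17 (camera adjusted p = 0.004). With an estimated correlation the adjusted p was 0.293, and without Ccnd2 the list did not pass (camera adjusted p = 0.053). With single mice left out the median ranged from −0.30 to −0.14. Cyclin D2 (Ccnd2), a G1 cyclin expressed in spermatogonia, was the member that passed, at 8.71 ± 0.425 CPM in controls and 5.28 ± 0.220 CPM in inhibitor mice (adjusted p = 0.032, edgeR). Pou3f1 (−0.98) and Mycn (−0.42) had the next smallest p values and did not pass. Etv5, Bcl6b and Lhx1, transcription factor genes known to respond to GDNF in cultured spermatogonia and named after their values were seen, had log2 fold changes of −0.13 (SE 0.123), 0.07 (SE 0.140) and −0.17 (SE 0.186). Here whole testes were collected after 5 days without injections, so these values do not show whether the genes responded in spermatogonia during treatment. Expression of these genes in other cell types could also mask a change, and was not tested. The list of stem cell-enriched markers also passed (7 of 10 lower, median −0.12, adjusted p = 0.029), with Ret as its passing member. It did not pass with an estimated correlation (adjusted p = 0.293), without Ret (adjusted p = 0.409), without inhibitor 1 or without inhibitor 3. Its members Id4, Eomes, Etv5, Bcl6b, Lhx1 and Tspan8 are also in the GDNF-responsive list, and Ret and Gfra1 in the GDNF family list. The results of these lists are therefore not independent. Id4, a marker of stem cells, was at 35.6 ± 2.95 and 33.2 ± 1.09 CPM, and Eomes had a log2 fold change of −0.80 (SE 0.401). Neither passed, and the limits given for Etv5, Bcl6b and Lhx1 hold for them too.

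Elongating spermatid genes rose as a list (18 of 20 members higher, median log2 fold change 0.08, camera adjusted p = 4.1e-04), and 3 passed adjusted over the list alone, none over all genes. The list did not pass with an estimated correlation (adjusted p = 0.293) or with the length and GC trend removed (adjusted p = 0.091, median 0.03). Akap4, a component of the sperm tail sheath, had a log2 fold change of 0.17, Cabs1 of 0.20, the protamine gene Prm2 of 0.16 and Fscn3 of 0.14. Genes of pachytene and later spermatocytes rose as well (13 of 20 higher, 6 adjusted over the list alone, median 0.07, adjusted p = 0.026), but not with an estimated correlation (adjusted p = 0.336), with the trend removed (0.436), without control 2 or without inhibitor 3. Tbpl1 was at 0.24, Pou5f2 at 0.26 and the testis-specific glycolytic genes Pgk2 and Ldhc at 0.19 and 0.13. Without Tbpl1 the list did not pass (camera adjusted p = 0.094). Round spermatid genes rose (17 of 20 higher, 1 adjusted over the list alone, median 0.06, adjusted p = 0.037), but not with an estimated correlation (adjusted p = 0.655) or without control 2, inhibitor 1 or inhibitor 2. With the trend removed the list turned direction, with a median of 0 (adjusted p = 0.722). Without Zpbp2 the list did not pass (camera adjusted p = 0.143). Zpbp2, which passed over the list alone, was at 0.27, and Dpy19l2 at 0.15, Lyzl1 at 0.21 and Catsper1 at −0.15 did not pass. Genes of meiotic entry and early prophase did not pass (17 of 27 higher, median 0.03, adjusted p = 0.244), with Spo11 at 0.28 and Hormad1 at 0.22. After removal of the trend that list was at −0.058, Hormad1 at −0.013 and Lyzl1 of the round spermatid list at −0.002.

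**Figure D2:**
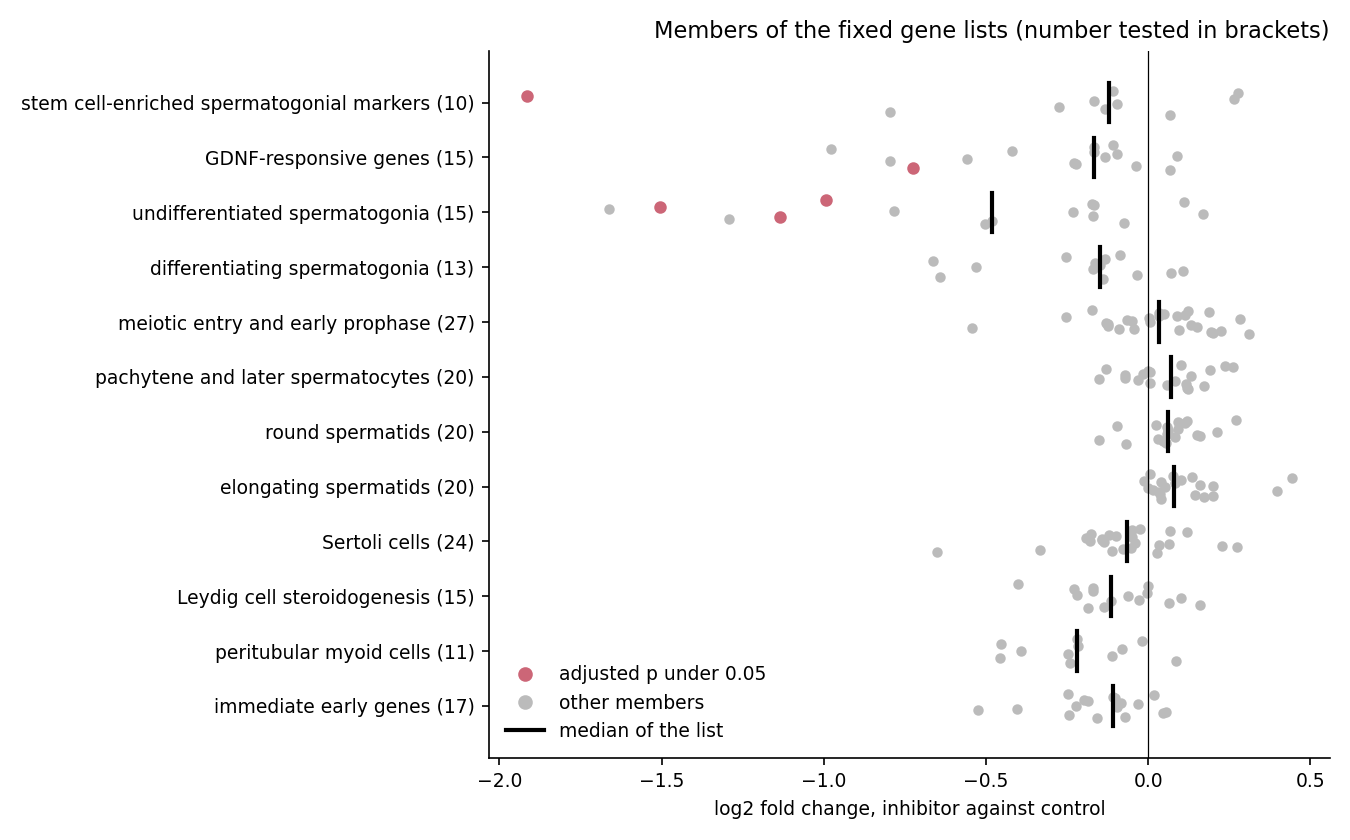
Log2 fold change of inhibitor against control mice (horizontal axis) for each tested member of 12 gene lists fixed in advance, with members past the adjusted threshold in red, the others in grey and the median of each list as a black bar. The median lies at −0.48 for undifferentiated spermatogonia and between 0.03 and 0.08 for the lists of meiotic cells and spermatids.

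The lists of testicular somatic cells did not pass. Sertoli cells, which nurse the germ cells and produce GDNF, had a median log2 fold change of −0.07 over 24 genes, of which 17 were lower (adjusted p = 0.271). Adjusted over the list alone, Cst9 (0.23) and Cst12 (0.28) were higher and Amh (−0.65), named after its values were seen, was lower. With the length and GC trend removed these were at −0.01, 0.03 and −0.55. Niche and paracrine factors had a median of −0.15 (adjusted p = 0.093), with the Notch ligand gene Jag2 at −0.42 and Wnt6 at −0.21. Leydig cell steroidogenesis stood at −0.12 (adjusted p = 0.186; Por −0.23, Nr5a1 −0.17) and cholesterol biosynthesis at −0.07 (0.271; Idi1 0.19). Peritubular myoid cells stood at −0.22 (adjusted p = 0.054; Mylk −0.22, Cnn1 −0.46) and endothelial cells at −0.10 (0.199; Eng −0.34, Vwf −0.15). Among the alternatives, the peritubular list passed without control 1, control 3 or inhibitor 3 but had a median of −0.07 (adjusted p = 0.534) without control 2. Others that passed were the Leydig list without control 1 or inhibitor 2, the niche list without control 1 or inhibitor 3, the cholesterol list without control 1 and the Sertoli list without inhibitor 3.

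Among blood and immune cells, macrophages had a median of −0.01, a mean of 0.03 and an upward test (adjusted p = 0.271; Aif1 0.20, Lyz2 0.32). Lymphocytes had a median of 0.11 (0.546; Cd4 0.72, Cd3d 0.34), and erythroid cells a median of 0.01 with a downward test (0.942; Alas2 0.06, Hba-a1 −0.05). Of the epididymal list, which marks tissue next to the testis, only 2 members, Ros1 (−0.09) and Rnase10 (−0.38), were expressed enough to be tested, too few for a list test. The mean log2 CPM of those 2 was −1.16 in inhibitor 3 and between 1.26 and 1.71 in the other libraries.

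Immediate early genes, which are induced within minutes of stimulation, fell as a list (14 of 17 lower, median −0.11, camera adjusted p = 0.026), although none of them passed alone, also when adjusted over the list alone. The estimated-correlation adjusted p was 0.524, the list did not pass without inhibitor 2, and it was at adjusted p = 0.108 with the length and GC trend removed. Without Jund the list did not pass either (camera adjusted p = 0.091). With single mice left out its median ranged from −0.22 to −0.07. Jund was at −0.19, Klf2 at −0.20, Klf4 at −0.10 and Fosl2 at −0.40. Genes of the mitotic cell cycle did not pass (26 tested, median −0.01, adjusted p = 0.372) and went both ways: adjusted over the list alone 4 were lower and 2 higher, with the proliferation marker Mki67 at −0.38 and Gins1 at 0.30. The p53 response (median −0.06, adjusted p = 0.271; Bax −0.38, Zmat3 0.24) and the heat shock and unfolded protein response (0.06, adjusted p = 0.138; Dnajb9 0.19, Ddit3 0.19) did not pass, and with the length and GC trend removed Dnajb9 was at 0.06 and Ddit3 at 0.01. Retinoic acid metabolism and response had a median of 0.00, a mean of −0.05 and a downward test (adjusted p = 0.942), with Crabp1 at −0.64 and Aldh1a1 at 0.20.

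A trend with transcript length ran through the comparison. Across 12889 genes, which are not independent replicates, the rank correlation of log2 fold change with transcript length was −0.383 and with GC content −0.304. When the genes were divided into 5 equal bins by length, the bin with the shortest transcripts had a median log2 fold change of 0.09 and that with the longest −0.08. The median transcript length was 1307.5 nt for the elongating spermatid list, 1651 nt for round spermatids and 3505 nt for undifferentiated spermatogonia. Within the inhibitor group the libraries differed: the rank correlation of each library's deviations with length was −0.261 in inhibitor 1, −0.390 in inhibitor 2 and 0.062 in inhibitor 3, against 0.316, 0.244 and 0.246 in the controls. On the first principal component (32.0% of variance) inhibitor 3 lay at −14.2, within the control range of −16.8 to −4.0, and inhibitors 1 and 2 lay at 23.3 and 22. With the trend removed, 6 genes were higher and 7 lower in the edgeR test, 9 of them among the 26 above, and the undifferentiated list had a median of −0.38 (camera adjusted p = 2.2e-11 with the preset correlation, and adjusted p = 0.121 with an estimated correlation). Of the 26 genes, 24 had a transcript length. The others, Daf2 and an unnamed locus, were left uncorrected and are among the 9.

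**Figure D3:**
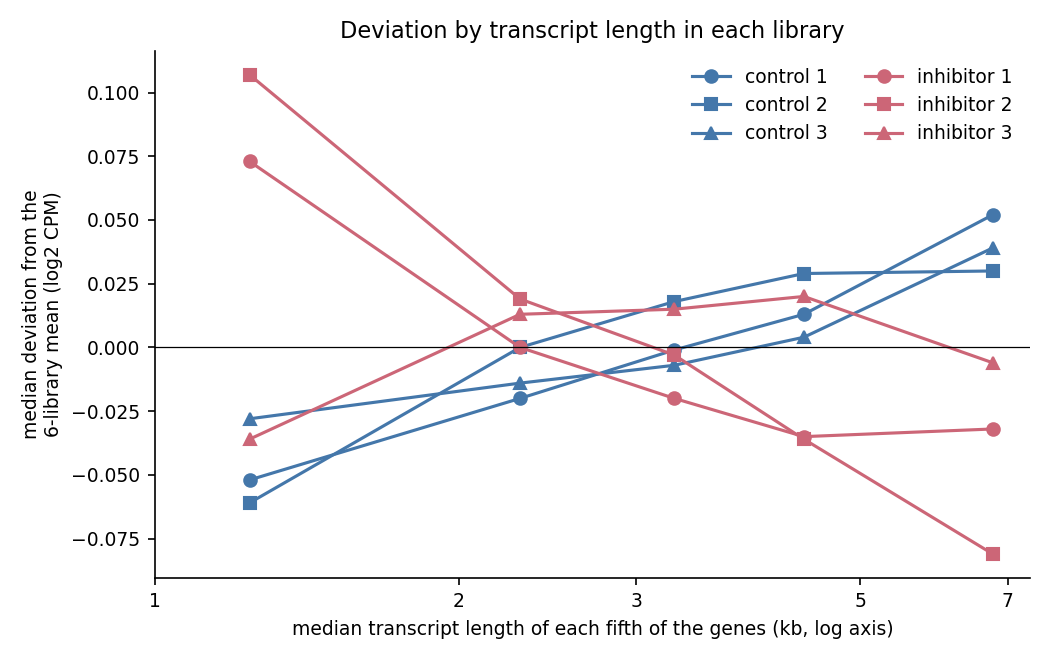
Median deviation of log2 CPM from the mean of the 6 libraries (vertical axis) for 5 equal bins of genes by transcript length (horizontal axis, median length of each bin in kb, log scale), with 1 line per library. The bin with the shortest transcripts deviates by 0.07 and 0.11 in inhibitors 1 and 2, and by −0.04 in inhibitor 3, next to −0.06 to −0.03 in the controls.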

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

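The tests that removed the length and GC trend or left out single members of lists were chosen after the results were seen; the others were set before the data were examined. The number of genes past the threshold moved with nearly every choice. Against 10 higher and 16 lower, there were 4 higher with library totals alone (23 lower), 58 and 57 with no filter on low counts, 3 and 7 with at least 50 counts in 3 libraries, 6 and 7 with the length and GC trend removed, 364 and 167 with DESeq2, 3 higher with limma-voom (11 lower), 0 and 0 with log2(FPKM + 1) and 0 and 1 with log2(FPKM + 0.1). RLE size factors (10 and 12) and removal of the 50 most abundant genes (10 and 15) stayed close. Library totals moved the median of all genes to −0.04, from 0.00. Leaving out each mouse gave 0 to 1470 higher and 0 to 935 lower; where the edgeR count was 0, 973 to 1124 genes were higher and 945 to 1085 lower at the unadjusted threshold. The causes of these changes were not tested, beyond the smaller number of genes or mice in some settings. With the mouse number as a replicate block, 0 genes were higher and 5 lower; deviations of same-numbered mice correlated at 0.158, −0.104 and 0.091, not all above 0.1, so the numbers were not treated as pairs. Of the 26 genes, 19 were called by DESeq2 and the other 7, Ret and Sox3 included, had no adjusted p there. The 21 named genes that passed kept their direction in every setting that gave a value. Ret had log2 fold changes of −2.01 to −1.80 with a mouse left out, and −0.25 with log2(FPKM + 1), where the added 1 compresses low values; its adjusted p ranged from 4.9e-04 to 0.157 over all settings. Of the lists, 5 passed with the trend removed, 3 without the member with the smallest p, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 6 with fry, against 8. With RLE size factors, no filter or the block, 10 lists passed, with the GDNF family and peritubular lists added. The undifferentiated list, at a median of −0.48, had adjusted p = 0.184 with the estimated correlation and 0.025 with fry, and 1.5e-11 to 0.184 over all settings. Of the 87 named genes, 33 shrank by more than 1.5 times or turned with the trend removed. They include Pgk2 (to 0.056), Ldhc (0.011), Zpbp2 (0.16), Dpy19l2 (0.082), Cabs1 (0.03), Prm2 (0.064), Klk1b8 (0.30), Jag2 (−0.245), Wnt6 (−0.13), Aldh1a1 (0.13), Nr5a1 (−0.078), Idi1 (0.11), Mylk (−0.076), Aif1 (0.07), Lyz2 (0.205), Ros1 (−0.033), Gins1 (0.14), Jund (−0.069), Klf2 (−0.13), Klf4 (−0.055), Etv5 (−0.084) and Lhx1 (−0.10). Some directions turned, where the direction of a list is that of its camera test. With the trend removed these were the meiotic entry list (−0.058), Hormad1 (−0.013), Lyzl1 (−0.002), Cst9 (−0.01) and Vwf (0.027), none of which had passed, and the round spermatid list, which had (median 0.00). The median of the GDNF family list also turned there, from −0.086 to 0.028, and with mice left out the medians of the p53 (−0.15 to 0.025) and macrophage (−0.068 to 0.15) lists crossed 0, while their tests kept direction. The retinoic acid list turned without Crabp1 (0.009), and the erythroid list with no filter (0.003). With single mice left out, medians ranged from −0.16 to −0.021 for Sertoli cells, −0.29 to −0.072 for peritubular cells, −0.21 to −0.066 for the niche list, −0.26 to −0.031 for endothelial cells, −0.30 to −0.14 for GDNF-responsive genes, −0.22 to −0.071 for immediate early genes, −0.091 to −0.025 for the X- and Y-linked list, 0.005 to 0.068 for meiotic entry, 0.022 to 0.079 for spermatocytes, 0.023 to 0.12 for round spermatids, 0.023 to 0.089 for heat shock, −0.10 to 0.059 for retinoic acid, −0.18 to 0.03 for Leydig cells, −0.16 to 0.047 for cholesterol biosynthesis and −0.96 to 0.41 for erythroid cells, and log2 fold changes from −0.026 to 0.23 for Gdnf, −0.047 to 0.15 for Bcl6b, −0.036 to 0.19 for Alas2, −1.16 to 0.34 for Hba-a1, −0.26 to 0.005 for Ros1 and −0.97 to 0.21 for Rnase10. A prior count of 0.5 in place of 2 moved no list level by more than the spread between mice. At a level of 1 CPM a library held 23.1 to 43.1 fragments, which limits the precision for genes such as Prtg and Foxf1.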

Other observations

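Lin28a and Trim71, which both fell, belong to the let-7 pathway, and Igf1r, which also fell, is a known let-7 target. A list of let-7 targets, drawn up after these genes had been seen to fall but before its own values were seen, was tested without the genes that passed. Its 24 tested members had a median log2 fold change of 0.002, with 13 higher and 11 lower (camera adjusted p = 0.193). These values met the bounds set in advance for a list that did not fall. Because members went both ways and the passing genes were left out, they do not decide whether single let-7 targets were affected. X-linked genes were examined after the X- and Y-linked spermatogonial list had been seen with the length and GC trend removed. Over 633 X-linked genes the median log2 fold change was −0.007 without the correction, where camera did not pass. With it the median was −0.076 (camera adjusted p = 7.5e-05, over this test and that of the let-7 list). With the correction, the median deviation of X-linked genes was 0.02, 0.07 and 0.04 in controls and −0.07, −0.04 and −0.01 in inhibitor mice. A lower output of the X chromosome is therefore a hypothesis that rests on the correction. Whole-testis RNA does not separate it from a changed mix of cell types that express X-linked genes unequally, which was not tested. Lower X output does not account for the 14 autosomal members of the undifferentiated list. They had a median of −0.32 with the same correction, a test chosen after the result was seen. For the X- and Y-linked list, lower X output and a changed mix of cell types both stay open.

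The tests of the following pattern, apart from the splits of the mice, were chosen after its result was seen. The undifferentiated spermatogonial list had a lower level in each inhibitor mouse than in any control. The length and GC trend was argued against as the whole cause, since the list passed with it removed (adjusted p = 2.2e-11, median −0.38, although adjusted p = 0.121 with an estimated correlation, against 0.184 before the removal), and none of 10000 random lists matched on expression, length and GC had so low a median (lowest −0.34). Dilution by RNA of other cells was argued against too, because the list also fell relative to Sertoli cell genes, with a change in the difference of the list means of −0.504 on the log2 scale and a group SD of at most 0.071. Fewer undifferentiated spermatogonia, or less of these RNAs per cell, may underlie it and cannot be told apart: the fold changes of the members had an SD of 0.597, wider than a uniform loss of cells would give, but expression of some members in other cells would widen it as well. The 6 mice allow 10 splits into 3 and 3, too few for a share under 0.05: the real split gave 26 genes against at most 10 in the others, and 8 lists against at most 9, and 1 split gave as many genes and 4 as many lists, the real one included.

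The trend of fold change with transcript length was weighed with tests set before their results were seen. A larger share of spermatid RNA, whose transcripts are short, was argued against only in part. The trend was also present within lists of somatic cell genes (rank correlation −0.323 over 79 genes, permutation p = 0.004). Within the spermatid lists it was −0.147 over 40 genes (permutation p = 0.365). The somatic result counts against spermatid RNA only where the listed genes are expressed in somatic cells alone, which was not tested. In controls Aif1 of the macrophage list stood at 320 CPM, against 1.91 for Cd68 and 10.8 for Csf1r. The permutation also treats genes as independent, although they come from the same mice. RNA or library quality that differs between libraries stays open. The 83 tested cytosolic ribosomal protein genes had a median log2 fold change of 0.118, above the bound set in advance for this explanation. That bound alone does not decide, because their transcripts are short, and short transcripts would be higher under any cause of the trend. A further condition, not part of the bound, was a rise with the trend removed, and the median there was 0.022. Without that removal, the mean deviation of these genes was 0.126 and 0.178 in inhibitors 1 and 2. In inhibitor 3 it was −0.086, within the control range of −0.102 to −0.047, so the rise was not shared by all inhibitor mice. RNA integrity is not given in the sources used here, so a technical and a treatment-related source of the trend both stay open.

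Guca2b was the single gene of the table with at least 10 fragments in every library of one group and 0 in the other, and it was followed up with tests set before their results were seen. Intestinal tissue carried into the control samples was argued against: of the other genes in a list of intestinal genes drawn up for this test, 0 were lost from the inhibitor libraries in the same way, and the abundant intestinal genes Fabp1 and Fabp2 had at most 5 fragments in any control. A change that takes in the neighbouring genes may be involved, but this stays open. Of the 2 tested genes within 100 kb, Foxj3 had a log2 fold change of −0.08 and Hivep3 of −0.77 (edgeR adjusted p = 0.108); the larger size, 0.774, lay between the bounds set for either reading. Guca2a, which lies between Foxj3 and Guca2b, had too few fragments to be tested. It had 5, 11 and 5 in the controls and 12, 7 and 7 in the inhibitor mice, so it was not lost. A difference in parentage or genetic background between the mice of the groups was not tested.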
